A study of Rattus norvegicus with 6 samples.

How the data were processed

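Small RNA was profiled in the trigeminal ganglion on the operated side of Sprague-Dawley rats, 14 days after chronic constriction injury of the infraorbital nerve (CCI-ION, 3 libraries) or a sham operation (3 libraries), per the labels. Groups and replicate numbers were taken from the sample titles. The design gives n = 3 per group but does not say outright that each library came from a separate animal, so p-values measure the spread between these libraries, which may in part be technical. The labels name a TruSeq RNA kit and total RNA. How small RNA was selected is not given in the sources used here.

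The authors deposited a table of raw counts for 650 mature miRNAs, with the sequence and length of each, and 1 file of RPM values per library. The reads were processed with cutadapt 1.14 and Bowtie 1.1.1 on the genome build rn6, per the submitters' processing notes. The read counter and the miRNA annotation are not given in the sources used here. The deposited RPM values equal the deposited counts times 1 constant per library. Whole reads were recovered from 100% of the RPM values within 0.01 read. The total behind each RPM constant was larger than the sum of the miRNA counts, and what it counts is not stated. No name or sequence was repeated in the deposited count table. Reads that match several miRNAs could have been split or counted more than once by the authors. Therefore miRNAs that differ from another listed miRNA by at most 2 bases over at least 19 bases are reported as uncertain. Sequences were compared from the first base, so matches at a shifted start or on the opposite strand are not flagged. The total miRNA counts ranged from 6420434 to 12560545 per library. A floor of 3 counts corresponds to 0.239 to 0.467 CPM. Floors cover counting error only, because the reads carry no molecular identifiers in the deposited values.

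Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (robust fit, TMM factors, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The filter kept 463 miRNAs and left out 187. Levels are TMM-scaled CPM, given as mean ± SD over 3 libraries, and log2 fold changes are CCI-ION over sham ± SE. Gene-wise results of DESeq2 1.42.0 and limma-voom (limma 3.58.1) served as alternatives. Both groups carry replicate numbers 1 to 3. Before the data were examined, the main fit was fixed as group alone. A fit with the replicate number as a block was fixed only as an alternative to compare with it. The pairing was then checked from the deviations of each library from its group mean in log2 CPM. Libraries with the same number correlated at 0.664 (number 1), 0.591 (number 2) and 0.457 (number 3), and each library correlated best with its own number. The other 6 combinations ranged from -0.614 to 0.167. Deviations within a group cancel, so these correlations are not independent, and 3 libraries per group allow few other matchings. The check used the same counts as the tests. Only after this check, and so after seeing the data, were the numbers treated as pairing the libraries. The value with the block is printed beside each result that it changes. What the number stands for, such as a shared day of surgery or library preparation, is not given in the sources used here. The block leaves 2 residual degrees of freedom, and the blocked fit leans on a variance shared across miRNAs (median prior degrees of freedom 54.5, against 3.3 without the block).

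Named miRNAs follow a rule set before the data were examined: up to 12 called miRNAs per direction with the smallest p, the 5 with the smallest p as values only where fewer than 5 were called, the 10 most abundant, the called members and the 2 most abundant members of each list, and miR-32-5p, which is known from published work on this pain model. The rule was applied to both fits. A total of 16 lists of miRNAs were fixed at the same time: neuronal, sensory neuron cluster, nerve injury induced, pain model literature, myeloid and lymphoid, erythroid, myelinating glia, fibroblast and mural, endothelial, skeletal muscle, epithelial, let-7, miR-17-92 and paralogs, miR-29, miR-30 and the Dlk1-Dio3 imprinted cluster. The let-7 list as fixed lacks let-7g. Members are shared between lists: miR-142, miR-146a, miR-146b, miR-155 and miR-223 stand in both the nerve injury and the leukocyte lists. Lists with at least 3 tested members (15) were tested with camera on log2 CPM (prior count 2, preset correlation 0.01), with camera using an estimated correlation and with fry. The share of counts held by each list was compared with a two-sided exact permutation test, for which the smallest possible p is 0.1.

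The procedure was tested on counts simulated from the fitted means and dispersions of each fit, with miRNAs drawn independently. Such counts follow the fitted model by construction, so they cannot show how often calls are false in these libraries. Without the block, 131 calls were made among 457 miRNAs of which 200 had been changed, 2 of them false. It recovered 14.9% of 1.5-fold, 82.1% of 2-fold and 97% of 4-fold changes. With the block, 174 calls were made with 196 changed, 4 of them false, and the recovered shares were 66.2%, 93.9% and 100%. Neighbouring miRNA genes were taken from RefSeq on the assembly GRCr8, which differs from rn6, so no coordinates are printed. A total of 432 mature miRNAs had a single locus there. Alternatives covered normalization, test, filter, dispersion, abundant miRNAs, threshold, the replicate block and leaving out each library. Scaling to the totals behind the RPM, a GC correction, a block for the libraries numbered 1, recovered reads, and leaving out both libraries of a number were added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.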

Results

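The trigeminal ganglion holds the cell bodies of the sensory neurons of the face. In CCI-ION, loose silk ligatures around the infraorbital nerve, a branch of the maxillary division, produce neuropathic pain in the rat, and in the sham operation the nerve is exposed without ligation. miRNA profiles of ipsilateral ganglia were available for 3 sham and 3 CCI-ION libraries on day 14. Total miRNA counts were 12560545, 10135844 and 10084327 in sham libraries 1 to 3, and 11014970, 6420434 and 7694056 in CCI-ION libraries 1 to 3. Between 558 and 593 miRNAs had at least 1 count in a library. The 10 most abundant miRNAs of each library held 65.0% to 67.2% of its counts, and miR-99a-5p alone held 19.2% to 24.6%. No pair of libraries within a group agreed within sampling noise (chi-square over degrees of freedom 164.6 to 732).

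The first principal component, with 49.3% of the variance, separated the 2 libraries numbered 1 from the other 4. The second, with 22.2%, separated CCI-ION from sham (two-sided exact permutation p = 0.1, the smallest possible). Exchanging the groups within pairs of the same number gave an exact sign-flip p of 0.25, also the smallest possible. The libraries numbered 1 were also the most deeply sequenced, with totals behind the RPM of 24025572 and 24259518 against 13793797 to 15228984 in the others.

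**Figure D1:**
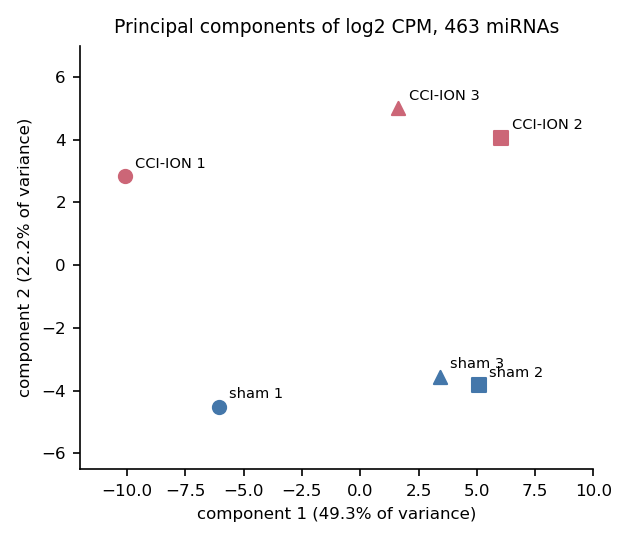
Scores of the 6 libraries on the first 2 principal components of log2 CPM over 463 miRNAs, coloured by group, with a marker shape per library number. Component 1 (49.3% of the variance) sets the libraries numbered 1 at negative scores, and component 2 (22.2%) has all sham libraries below 0 and all CCI-ION libraries above 0.

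The comparison of CCI-ION with sham asks which miRNAs differ in the injured-side ganglion 14 days after the nerve injury. The 2 miRNAs called lower belong to a cluster of neighbouring miRNAs, miR-216a, miR-216b and miR-217, known mainly from the pancreas. miR-216b-5p (AAATCTCTGCAGGCAAATGTGA) fell from 84.9 ± 7.17 CPM in sham to 23.4 ± 2.73 in CCI-ION (SD, n = 3 each), a log2 fold change of -1.86 ± 0.16 with an edgeR adjusted p of 0.00246. miR-216a-3p (CACAGTGGTCTCTGGGATTATG) fell from 33.5 ± 4.58 to 11.3 ± 1.94 CPM (log2 fold change -1.57 ± 0.20, edgeR adjusted p = 0.015). miR-219a-1-3p (AGAGTTGCGTCTGGACGTCCCG), the partner strand of a miRNA family of myelinating glia, rose from 4.77 ± 1.08 to 15.15 ± 2.08 CPM (1.66 ± 0.24, edgeR adjusted p = 0.0239). Each of these 3 miRNAs had no overlap between groups, so each also moved the same way in 3 of 3 pairs of libraries.

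Without the replicate block these 3 were the only miRNAs called by edgeR among 463, while 46 had an unadjusted p under 0.05 and DESeq2 called 9. With the replicate block edgeR called 54 miRNAs, 28 higher and 26 lower in CCI-ION. DESeq2 with the block also called 43 of these 54, limma-voom with the block 38, and all 3 tools shared 36. List members said below to rise or fall with the block are edgeR calls. For example, miR-124-5p (adjusted p = 0.157 and 0.112) and miR-30a-5p (0.0597 and 0.143) were called with the block by neither DESeq2 nor limma-voom. Nor did limma-voom call miR-155-5p (0.0551), miR-221-3p (0.055) or miR-434-5p (0.112), and DESeq2 did not call miR-412-3p (0.219). Of the 54, 53 moved the same way in 3 of 3 pairs, and 31 had no overlap between groups. The blocked fit favours miRNAs that move alike within these pairs, so their agreement is no separate support. Over all tested miRNAs 64 (13.8%) had no overlap, where chance gives 10% if the libraries are not paired. Without the block, leaving out sham library 2 or 3 or CCI-ION library 2 or 3 left 1 call, miR-216b-5p, and leaving out CCI-ION library 1 gave 7 calls. With the block, leaving out both libraries numbered 2 gave 31 calls, 30 of them among the 54, and leaving out both numbered 3 gave 5, all among the 54: miR-216b-5p, miR-216a-3p, miR-216a-5p, miR-217-5p and miR-219a-1-3p. When libraries were scaled to the totals behind the RPM, the block gave 6 higher and 152 lower, with the median of all miRNAs at -0.345, and under upper quartile factors it gave 43 higher and 17 lower.

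The other tested members of this cluster had the same direction with the block. miR-217-5p averaged 59.9 ± 22.9 CPM in sham and 20.8 ± 3.25 in CCI-ION (log2 fold change with the block -1.46 ± 0.15). Its edgeR adjusted p was 2.71e-10 with the block and 0.125 without it, and limma-voom with the block gave 0.00413. miR-216a-5p averaged 10.28 ± 2.68 and 2.34 ± 1.24 CPM (-2.12 ± 0.28 with the block). Its edgeR adjusted p was 2.15e-08 with the block and 0.103 without it, and limma-voom with the block gave 0.00552. The size of the blocked p-values thus depended strongly on the tool.

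**Figure D2:**
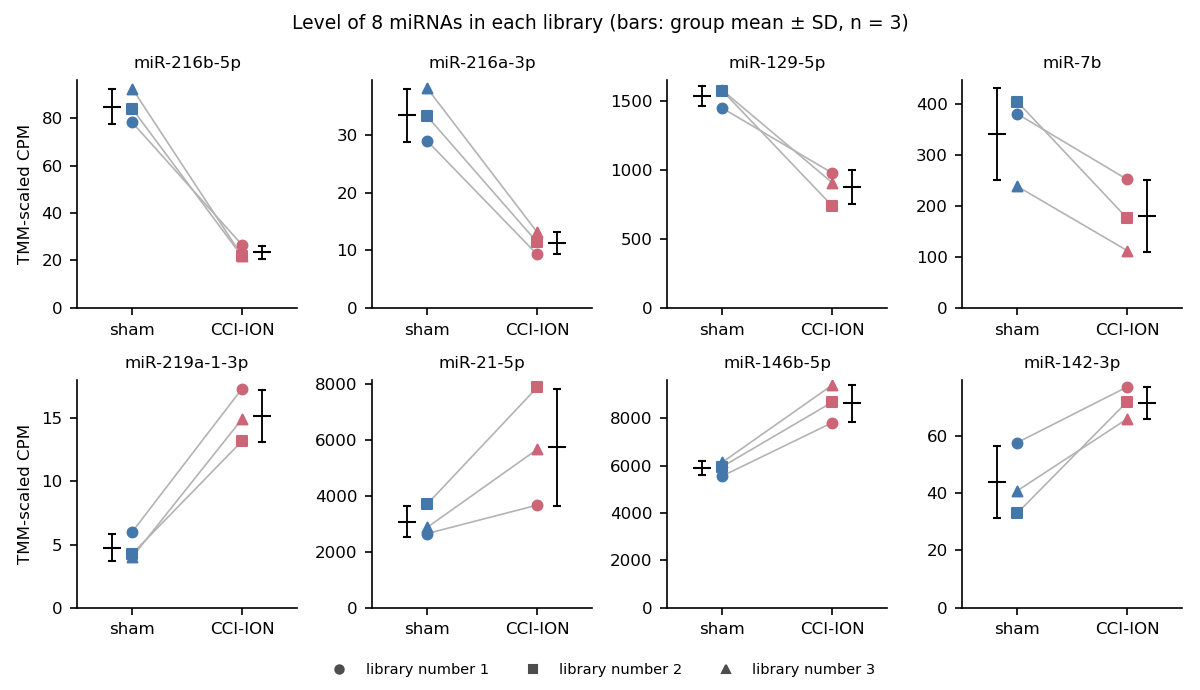
TMM-scaled CPM of 8 miRNAs in each library, sham on the left and CCI-ION on the right, with grey lines joining libraries of the same number and black bars giving the mean ± SD of 3 libraries. miR-216b-5p, miR-216a-3p, miR-129-5p and miR-7b are lower in CCI-ION in all 3 pairs, and miR-219a-1-3p, miR-21-5p, miR-146b-5p and miR-142-3p are higher in all 3 pairs.

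Of 28 tested neuronal miRNAs, 8 fell with the block and none rose: miR-129-5p, miR-7a-5p, miR-7b, miR-124-3p, miR-124-5p, miR-128-3p, miR-138-5p and miR-218a-5p. Without the libraries numbered 2, 4 neuronal members were called with the block, and without those numbered 3, 0. miR-129-5p fell from 1531 ± 74.2 to 873.9 ± 122.2 CPM (log2 fold change -0.82 ± 0.11 with the block). Its edgeR adjusted p was 3.81e-08 with the block and 0.0908 without it, and limma-voom with the block gave 0.00576. miR-7b, uncertain like miR-7a-5p because their sequences are close, fell from 340.5 ± 89.6 to 179.8 ± 69.7 CPM (-0.96 ± 0.12, adjusted p with the block 1.6e-08 with edgeR and 0.00576 with limma-voom). miR-124-3p, the classical miRNA of neurons, fell from 251 ± 9.28 to 180 ± 18.9 CPM (-0.48 ± 0.11, adjusted p with the block 0.000927 with edgeR and 0.0232 with limma-voom). miR-9a-5p, the most abundant member, stood at 13124 ± 1893 and 12240 ± 2591 CPM and was not called. Adjusted over the list alone, 10 members passed with the block and 1 without. The list median was -0.27, with 25 of 28 members negative (camera adjusted p = 1.5e-05, and 0.164 with an estimated correlation). Under scaling to the totals behind the RPM the list median was -0.59, where the median of all miRNAs was -0.338. These miRNAs held 2.87% ± 0.09 of the counts in sham and 2.36% ± 0.14 in CCI-ION (n = 3 each, two-sided exact permutation p = 0.1, the smallest possible; 0.4 adjusted over 16 lists).

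Among miRNAs known to rise in ganglia or nerve after axotomy, 6 of 25 tested rose with the block: miR-21-5p, miR-142-3p, miR-146a-5p, miR-146b-5p, miR-155-5p and miR-221-3p. Without the libraries numbered 2, 3 rose, and without those numbered 3 the block called 0 members of this list. miR-21-5p, widely induced by injury, rose from 3077 ± 555 to 5727 ± 2100 CPM (log2 fold change with the block 0.84 ± 0.11). Its edgeR adjusted p was 5.63e-08 with the block and 0.316 without it, and limma-voom with the block gave 0.00753. One member, miR-34a-5p, which p53 induces, fell from 482.9 ± 81.5 to 340.2 ± 88.9 CPM (-0.53 ± 0.11, edgeR adjusted p = 0.000204). Adjusted over the list alone, 8 members passed with the block and 0 without. The list median was 0.20, and -0.16 when libraries were scaled to the totals behind the RPM, so the direction holds relative to other miRNAs (camera adjusted p = 0.00417; adjusted p = 0.235 with an estimated correlation). Its share of counts was 2.12% ± 0.06 in sham and 2.65% ± 0.22 in CCI-ION (n = 3 each, exact permutation p = 0.1).

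Leukocyte miRNAs overlap with that list, and 5 of 13 tested rose with the block while none fell; without the libraries numbered 2 the block called 2 of them, and without those numbered 3, 0. miR-146b-5p, a brake on inflammatory signalling, rose from 5885 ± 296 to 8623 ± 794 CPM (log2 fold change with the block 0.55 ± 0.09). Its edgeR adjusted p was 1.36e-05 with the block and 0.156 without it, and limma-voom with the block gave 0.00691. The other 4 were miR-146a-5p (2190 ± 101 to 2889 ± 135 CPM), miR-142-3p, found in blood-derived cells (43.8 ± 12.6 to 71.5 ± 5.56 CPM), miR-155-5p and miR-342-3p. miR-146a-5p and miR-146b-5p have near-identical sequences and are uncertain. The myeloid miR-223-3p was low, at 5.59 ± 1.52 and 6.72 ± 1.89 CPM, and was not called. Adjusted over the list alone, 5 members passed with the block and 1 without. The list median was 0.38, 0.25 without sham library 3, and 0.05 under scaling to the totals behind the RPM (camera adjusted p = 0.00118; adjusted p = 0.164 with an estimated correlation). The list held 0.842% ± 0.024 of the counts in sham and 1.18% ± 0.05 in CCI-ION (n = 3 each, exact permutation p = 0.1).

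Of 8 tested skeletal muscle miRNAs, listed as markers of muscle attached to the dissected tissue, 2 fell with the block, and 0 without the libraries numbered 3. miR-1b fell from 8386 ± 2939 to 5905 ± 2511 CPM (log2 fold change -0.54 ± 0.10, edgeR adjusted p with the block 2.69e-05), and miR-133a-3p fell from 76.8 ± 11.5 to 49.5 ± 8.95 CPM (-0.64 ± 0.13, edgeR adjusted p with the block 0.000115). Both are uncertain, having near-identical copies in miR-1-3p and miR-133b-3p. The other 6 of 8 tested members had negative values and were not called. Adjusted over the list alone, 3 members passed with the block and 0 without. The list median was -0.49, and -0.29 without CCI-ION library 3 (camera adjusted p = 0.00417; adjusted p = 0.542 with an estimated correlation), and the camera call was lost without sham library 3 (adjusted p = 0.052) or CCI-ION library 1 (0.077). Under scaling to the totals behind the RPM the list median was -0.87, where the median of all miRNAs was -0.338. Muscle miRNAs held 0.908% ± 0.273 of counts in sham and 0.642% ± 0.245 in CCI-ION (n = 3 each, exact permutation p = 0.3).

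In the Dlk1-Dio3 imprinted cluster, a large maternally expressed group of miRNAs, 11 of 72 tested members rose with the block and 3 fell. Without the libraries numbered 2, 7 were higher and 1 lower, without those numbered 1, 10 were higher and 0 lower, and without those numbered 3, 0 were called. Those that rose included miR-494-3p (180.9 ± 26.4 to 287.5 ± 75.6 CPM), miR-540-3p (113 ± 20.6 to 175.5 ± 50.0 CPM), miR-409b, miR-541-5p (875.7 ± 81.9 to 1216 ± 140 CPM), miR-433-3p, miR-412-3p and miR-3072. Those that fell were miR-136-3p, miR-434-5p and miR-376b-5p, the last uncertain for its sequence close to that of miR-376c-5p. The most abundant members, miR-127-3p (27431 ± 5447 and 23973 ± 2996 CPM) and miR-379-5p, were not called. Adjusted over the list alone, 14 members passed with the block and 0 without. The list median was 0.04, from 0.029 without CCI-ION library 3 to 0.111 without sham library 2, and -0.30 under scaling to the totals behind the RPM (camera adjusted p = 0.0216; adjusted p = 0.235 with an estimated correlation). The camera call was lost with the replicate block (adjusted p = 0.0789, though 0.025 with the block without the libraries numbered 1), and without sham library 3 (0.084) or CCI-ION library 3 (0.16).

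**Figure D3:**
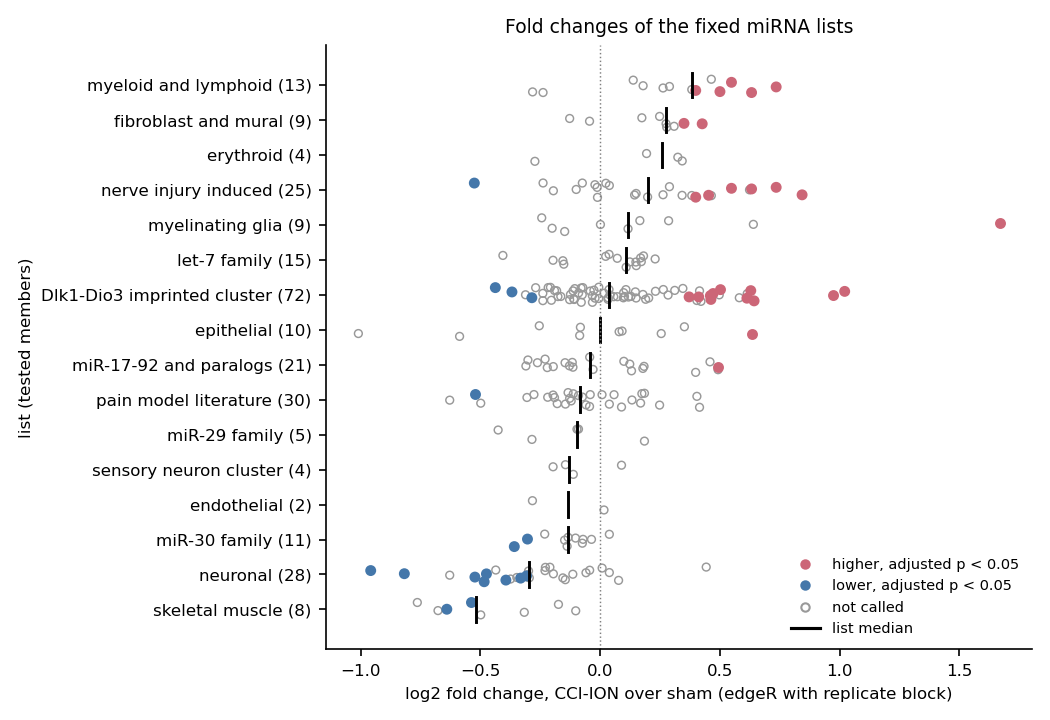
Log2 fold changes (CCI-ION over sham, edgeR with the replicate block) of the tested members of 16 miRNA lists, with the number of tested members in brackets. Filled points are called members (red higher, blue lower), open points were not called, and black bars are list medians. Skeletal muscle and neuronal lists have the lowest medians (-0.52 and -0.30), and the leukocyte list the highest (0.38), all relative to the other miRNAs. Under scaling to the totals behind the RPM, every list with a set test except the leukocyte list (0.04) has a median below 0.

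No other list was called, and of the members of these lists called with the block, only miR-219a-1-3p was also called without the libraries numbered 3. The sensory neuron cluster of miR-183, miR-96 and miR-182 had a median of -0.12 over 4 tested members (-0.18 without sham library 1 and -0.035 without CCI-ION library 2, camera adjusted p = 0.486), with miR-182 at 22976 ± 3595 and 24522 ± 4587 CPM and miR-183-5p at 15770 ± 1376 and 14253 ± 999 CPM. Of 30 tested miRNAs from the pain model literature, 1 fell with the block, miR-7a-5p (median -0.07, from -0.141 without sham library 1 to -0.014 without sham library 2, camera adjusted p = 0.401). Among myelinating glia markers, 1 of 9 rose, miR-219a-1-3p, while miR-338-5p and miR-204-5p were not called (camera adjusted p = 0.48). Among fibroblast and mural markers 2 of 9 rose with the block, miR-10a-5p and miR-199a-5p (camera adjusted p = 0.341, with the block 0.0589, and 0.0055 with the block without the libraries numbered 3). Of 10 epithelial markers 1 rose with the block, miR-205, from 56.6 ± 0.467 to 88.3 ± 9.29 CPM (camera adjusted p for the list 0.809). miR-375-3p varied between libraries, at 184.3 ± 69.2 and 106.2 ± 86.8 CPM. edgeR did not call it (adjusted p = 0.789, with the block 0.213), while with the block DESeq2 (adjusted p = 0.0357) and limma-voom (0.0312) called it lower, as did edgeR without CCI-ION library 1 and without the block (0.0217). Erythroid markers (4 tested, camera adjusted p = 0.423) and the let-7 family (15 tested, 0.486) had no called member, nor did the miR-29 family (5 tested, 0.341). The miR-17-92 group had 1 of 21 higher with the block, miR-20a-5p, which is uncertain because its sequence is close to those of miR-17-5p and miR-20b-5p (camera adjusted p = 0.917). The miR-30 family had 2 of 11 lower with the block, miR-30a-5p and miR-30e-5p, both uncertain because their sequences are close to each other and to miR-30d-5p (0.127). The 2 endothelial members, miR-126a-3p and miR-126a-5p, were not called, and the list was too short for a set test. Adjusted over the list alone, the block gave 0 calls in the sensory neuron, erythroid and let-7 lists, 1 each in the pain literature, glia, epithelial, miR-17-92, miR-29 and endothelial lists, 2 in the miR-30 family and 4 in the fibroblast list. The let-7 family held 19.7% ± 0.879 of miRNA counts in sham and 21.6% ± 0.484 in CCI-ION (n = 3 each, exact permutation p = 0.1), while its median log2 fold change was 0.11 and, under scaling to the totals behind the RPM, -0.24. That median was 0.012 without CCI-ION library 1. Leaving out 1 library made some of these lists pass camera: erythroid (adjusted p = 0.029) and miR-30 (0.034) without sham library 1, and fibroblast (0.03) and miR-30 (0.028) without CCI-ION library 3.

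The most abundant miRNAs were not called in either fit. miR-99a-5p stood at 220034 ± 9315 CPM in sham and 217038 ± 17843 in CCI-ION. miR-26a-5p, let-7i-5p, miR-27b-3p, let-7f-5p, let-7g-5p, let-7c-5p and miR-143-3p had edgeR adjusted p-values between 0.857 and 0.993.

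miR-32-5p (TATTGCACATTACTAAGTTGCA) was named beforehand, and its level depended on the scale. On the deposited RPM scale it averaged 67.7 ± 11.1 in sham and 43.8 ± 4.92 in CCI-ION (n = 3 each), 0.648 times the sham level, with no overlap between groups (two-sided exact permutation p = 0.1, the smallest possible). Among miRNA counts it averaged 111.1 ± 29.2 and 90.8 ± 14.6 CPM (n = 3 each, exact permutation p = 0.5) and was not called by edgeR (log2 fold change -0.29 ± 0.22, adjusted p = 0.833; with the block -0.28 ± 0.12, adjusted p = 0.145). Leaving out single libraries moved it from -0.42 (without sham library 2) to -0.05 (without sham library 1), and to -0.16 without CCI-ION library 3. With the block it ranged from -0.42 without the libraries numbered 2 to -0.17 without those numbered 1, and it was called in none of these. Scaled to the totals behind the RPM it was not called without the block (-0.63 ± 0.21, edgeR adjusted p = 0.157) and was lower with it (-0.62 ± 0.15, edgeR adjusted p = 0.00288), where the median of all miRNAs was -0.345.

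The scales differ because miRNA counts made up 61.8% ± 8.25 of the total behind the RPM in sham and 49.0% ± 5.87 in CCI-ION (n = 3 each). This share was lower in CCI-ION in 3 of 3 pairs, and the groups overlapped (two-sided exact permutation p = 0.2, the smallest possible being 0.1).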

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

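The settings scaled to the totals behind the RPM, corrected for GC or blocked for the libraries numbered 1, and all settings combined with the replicate block, were chosen after seeing the data. Without the block 3 miRNAs were called (1 higher, 2 lower). RLE factors, limma-voom, a CPM minimum of 10, leaving out the 5 most abundant and a non-robust fit also gave 3. Recovered reads gave 3 as well, but they equal the deposited counts, so this could not come out otherwise. Upper quartile factors and library totals only gave 0 higher and 2 lower. DESeq2 gave 9 (4 higher, 5 lower), no filter 6 (5 lower) and scaling to the RPM totals 6 (5 lower). The replicate block gave 54 (28 higher, 26 lower) and the block for the libraries numbered 1 gave 33 (20 higher, 13 lower). Leaving out each library gave 1 to 7 calls (0 to 2 higher, 1 to 5 lower). From the blocked 54, the fit with no replicate block gave 3 (1 higher, 2 lower). With the block, upper quartile factors gave 43 higher and 17 lower, limma-voom 17 lower, leaving out the 5 most abundant 16 lower, a non-robust fit 16 lower, and RPM totals 158 (6 higher, 152 lower). Leaving out both libraries of a number gave 5 to 45 (1 to 26 higher, 4 to 19 lower; 31, 16 higher and 15 lower, without those numbered 2), with fewer libraries in each fit. All 54 kept their sign in every blocked setting in which they were tested, though these settings refit the same libraries. Of them, 32 stayed called under RPM totals, 44 after GC correction and 5 without the pair numbered 3. These 5 were the 4 of the miR-216 and miR-217 group and miR-219a-1-3p. Of the lists, 5 were called with camera, 0 with an estimated correlation and 1 with fry (leukocyte). With the block these were 4, 0 and 0. The set test does not alter the list medians, which stayed at -0.27 (neuronal), 0.198 (nerve injury), 0.382 (leukocyte), -0.489 (muscle) and 0.039 (Dlk1-Dio3). The Dlk1-Dio3 call was also lost without a filter (median 0.011), with a CPM minimum of 10 (0.004), under RPM totals (-0.305), with the replicate block (0.039) and with the block for the libraries numbered 1 (0.044). Leaving out libraries gave 3 to 7 lists. List medians then ranged from -0.036 to 0.681 (erythroid), 0.092 to 0.381 (fibroblast), -0.674 to -0.287 (muscle), -0.153 to -0.063 (miR-30), 0.029 to 0.111 (Dlk1-Dio3), 0.012 to 0.162 (let-7), -0.18 to -0.035 (sensory neuron), -0.141 to -0.014 (pain literature), -0.162 to 0.134 (epithelial), -0.082 to 0.091 (miR-17-92), -0.284 to -0.039 (miR-29), -0.07 to 0.173 (glia), 0.254 to 0.413 (leukocyte), 0.17 to 0.265 (nerve injury) and -0.374 to -0.204 (neuronal). In the edgeR fit with TMM and filterByExpr the block changed no other camera call; without a filter it also ended the nerve injury call (median 0.143, adjusted p = 0.053 against 0.039 without the block), and with fry it ended the leukocyte call (0.066 against 0.017). For shares, 4 lists had no overlap between groups, 2 as a share of the RPM totals, and 4 to 7 without each library.

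miR-32-5p ranged from -0.418 to -0.054 without each library (-0.424 to -0.17 with the block, without each pair) and was called only with RPM totals and the block together (-0.62). A change of sign was counted where either value was called or the value moved by over 1 SE. By that measure 12 uncalled miRNAs changed sign under RPM totals, which moved the median of all miRNAs to -0.338 and so lowers every value alike: miR-26a-5p -0.317, let-7i-5p -0.19, let-7f-5p -0.238, let-7c-5p -0.19, miR-182 -0.254, miR-451-5p -0.043, miR-204-5p -0.207, miR-199a-3p -0.064, miR-126a-3p -0.354, miR-25-3p -0.215, miR-30c-5p -0.295 and miR-379-5p -0.236. miR-486 ranged from -0.359 (without CCI-ION library 1) to 0.713 without each library. Except for the RPM totals and the smaller fits, the cause of these changes was not tested. Summing repeated names was not run, as no name was repeated. Using per-library counts in place of the table was run only as the recovered reads, which hold the same counts. Depth limits low miRNAs: 3 counts are 0.467 CPM in the smallest library.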

Other observations

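The replicate block as an alternative, the lists and their set tests were fixed beforehand. The other tests in this part were chosen only after the result was seen. Among miRNAs outside the fixed lists, 5 rose and 10 fell with the replicate block. Those that rose were miR-341 (117.2 ± 26.8 CPM in sham and 197.6 ± 23.6 in CCI-ION, n = 3 each), miR-351-5p (457.8 ± 32.8 and 617.3 ± 14.1), miR-184, miR-139-5p and miR-1188-5p. miR-341 and miR-1188 lie beside miR-127 and miR-433 of the Dlk1-Dio3 cluster on the assembly GRCr8. Those that fell were the 4 members of the miR-216 and miR-217 group, miR-215 (7.18 ± 4.05 and 2.1 ± 1.07 CPM), miR-3571, miR-3556b, miR-6321, miR-598-3p and miR-1843a-5p. miR-3571 lies beside miR-133a. miR-3556b is the reverse complement of nearly all of miR-29c-3p. It was low (2.72 ± 0.281 and 1.33 ± 0.454 CPM) and not called with the block by DESeq2 (adjusted p = 0.419) or limma-voom (0.124). miR-6321 (1.57 ± 0.847 and 0.567 ± 0.498 CPM) had 2 counts in CCI-ION library 1, under the floor of 3. With the block limma-voom called it (adjusted p = 0.0427) and DESeq2 did not (0.356). Over 40 groups of neighbouring miRNAs (within 50000 bases), 2 were called by camera. The miR-216a, miR-216b and miR-217 group had 4 of 4 members lower with a median log2 fold change of -1.71. Its adjusted p was 1.43e-08 with camera, 0.115 with an estimated correlation and 0.00276 with fry. With the block these were 2.13e-05, 0.809 and 0.109. Members include both arms of miR-216a, so they are not independent. The group of miR-1, miR-133a, miR-133c and miR-3571 had 5 of 5 lower (camera adjusted p = 0.00622, and 0.77 with an estimated correlation). With the block these values were 0.00784 and 0.809. The sequence of miR-133c is the reverse complement of nearly all of miR-133a-3p. That of miR-3571 likewise holds the reverse complement of nearly all of miR-1-3p, so the members are not independent.

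The splits of the libraries were too few for a share under 0.05. Without the block the real grouping gave 3 calls and the other 9 splits at most 2, so 1 of 10 splits gave as many. With the block the real grouping gave 54 calls and the other 3 assignments within pairs 0, so 1 of 4 gave as many. For lists, 2 of 10 splits gave 5 called lists, the real one and the one that exchanges the groups in pairs 2 and 3, which parts as many pairs. With the block the real grouping gave 4 lists and the others at most 2.

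miR-216a, miR-216b and miR-217 fell together. Library bias by GC content is argued against: with a GC offset and the block the median of the 4 members was -1.68 (range -2.09 to -1.45). A loss of neurons of all kinds would lower the neuronal list about as much, if all neurons make this group alike. That condition was not tested. With the block the neuronal median was -0.30 (quartiles -0.40 to -0.14), and -0.62 under scaling to the totals behind the RPM. Under that condition these values argue against such a loss, with a cut-off set after the result was seen. A loss of a particular cell type, a change of transcription after the injury and pieces of neighbouring tissue in the dissection stay open and were not tested.

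With the block, 8 of 28 neuronal and 2 of 8 muscle miRNAs were called lower and 5 of 13 leukocyte miRNAs higher, and none of these lists passed camera with an estimated correlation (adjusted p = 0.164, 0.542 and 0.164 without the block). A lower share of neurons alone would raise muscle and leukocyte markers alike. The muscle median lay -0.90 from the leukocyte median (exact permutation over members p = 0.000413, and members are not independent). These lists were compared after camera had called them in opposite directions in the same libraries. A small p was therefore built in, and it does not decide the question. Less muscle in the CCI-ION tissue stays open: the 6 muscle members of at least 10 CPM had a common log2 fold change of -0.44 (heterogeneity p = 0.0574, median within-group correlation 0.33, with miR-1b, the most abundant, at 8386 and 5905 CPM). More leukocytes stays open as well: all 7 leukocyte members of at least 10 CPM had positive values, from 0.18 for miR-150-5p to 0.73 for miR-142-3p (heterogeneity p = 0.0474, median within-group correlation -0.37), and unequal sizes do not decide it, since miR-146b-5p, at 5885 CPM in sham, is not restricted to leukocytes. Induction within resident cells was not tested and may also contribute.

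The libraries numbered 1 stood apart on component 1, with a gap of 0.48 of its range. Counting noise from unequal miRNA counts is argued against: after thinning to 6420434 counts per library the gap was 0.58 (0.93 to 1.36 times the original over 500 bootstraps of the miRNAs). Total sequencing depth cannot be told apart from the number, since the smaller total behind the RPM of these libraries was 1.58 times the largest of the other 4. GC content also stays open, since component 1 loadings followed GC (Spearman rho 0.50 across miRNAs, which are not independent) while the gap after GC correction was 0.66 (0.84 to 1.7 times the original). A shared batch behind the number was not tested, because the labels do not say what the numbers mark, and no biological explanation was tested.

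Among the blocked calls the 28 higher miRNAs had a mean GC of 51.8% ± 10.1 and the 26 lower 44.5% ± 8.5 (permutation p = 0.0055), and 44 of the 54 stayed called after GC correction. The permutation treats miRNAs as independent, which they are not. Across all 463 tested miRNAs, log2 fold change and GC had a Spearman rho of 0.18 with the block and 0.17 without it.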
